A study of Homo sapiens with 3 samples.

How the data were processed

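The data were 3 libraries from human 293T cells: 2 eCLIP libraries from cells that stably express METTL5-HA and 1 Input library labelled wild type. Per the labels' protocols, cells were crosslinked with UV light, lysed and treated with RNase I, complexes were pulled down with anti-HA beads, and RNA was ligated to adapters, run on a gel, recovered from the part above the size of the protein and reverse transcribed. A random tag was part of the adapter. Whether it was used to remove duplicate reads is not given in the sources used here. The submitters' processing notes name STAR and hg19, without versions or roles.

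The deposited table gives, per the file headers, a count for each position of 4 rRNAs in each library, 7218 positions in all. The authors deposited these counts without scaling. They were treated as read depths, in which a read is counted at each position it covers. Steps up in eCLIP depth were matched by steps down 75 nt later (correlation across positions 0.991 and 0.996 on 18S, 0.593 and 0.780 on 28S, the highest of all distances from 20 to 200 nt), so 75 nt was taken as the span of a read, and summed depth divided by 75 as the number of reads. How the table was made and whether depth was limited are not given in the sources used here. The values themselves stop short of 8000 in all libraries. Positions are along the rRNA sequences, counted from 1. All 5 annotated 18S genes (such as RNA18SN5) have the length of the table's 18S, and RNA28SN5 that of its 28S. All 17 genes RNA5S1 to RNA5S17 have the length of its 5S, and none of the 5 annotated 5.8S genes has that of its 5.8S. The rRNA genes are near-identical copies, so the counts cannot be assigned to a copy. These names come from a GRCh38 table, and no genomic coordinates are given. All value columns were used. Columns named for the first and second immunoprecipitate were taken as the eCLIP samples of the same number.

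Depth per sample was a sum of 17574237 in eCLIP replicate 1, 6930845 in eCLIP replicate 2 and 42783485 in Input. Shares of depth have exact (Clopper-Pearson) 95% binomial intervals on depth divided by 75, which cover counting error only. Counts were summed in windows of 50 nt. A read is therefore counted in a window at each position it covers, up to 50 times, and the tests take these sums as counts. edgeR 4.0.16 (R 4.3.3) tested eCLIP against Input with its quasi-likelihood test on all 3 libraries, with TMM scaling, filterByExpr and Benjamini-Hochberg adjustment at 0.05. This fit has 1 residual degree of freedom and rests on the spread of the 2 eCLIP libraries. Its estimated prior degrees of freedom were infinite, so each window took the quasi-likelihood dispersion of the trend across windows. Windows also share reads with their neighbours. Nothing says that the eCLIP libraries came from separate cultures, so p-values measure only the spread between these samples. The test was run on simulated data: 20 sets of the 147 windows, 40 changed per set, drawn from the Input profile with the real library totals and the common dispersion. Of windows changed 16-fold, 98.0% of the raised and 99.5% of the lowered were called. Of windows changed 4-fold, 63.5% and 71.0% were called. Of unchanged windows 0.654% were called. The simulation had no ceiling, and its libraries had no common read coverage between neighbouring windows. It raised and lowered windows in equal numbers, which suits TMM, while 51 windows of the data were called lower and 5 higher. Its rates therefore need not hold where changes lie mostly in the same direction. All simulated windows had the common dispersion of 0.0877, while the negative binomial trend of the real fit gave 0.123 for the deep 28S window 2401 to 2450. The quasi-likelihood dispersions of the real fit were not recorded. That window had an edgeR log2 fold change of 2.67 and was not called. The simulated rates therefore need not hold for deep 28S windows.

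Log2 ratios per replicate used TMM-scaled counts with a pseudocount of 1 count. The m6A site was placed 37 nt before the last base of 18S, the NAT10 site 27 nt and the DIMT1 pair 19 and 18 nt before it. The decoding-centre and helix 31 sequences, also chosen as landmarks, were not located, since no rRNA sequence was used here. The regions named were fixed by rule before the data were examined: each rRNA, the landmarks, and up to 10 merged regions in each direction with the largest mean log2 fold change among windows past the threshold and changed alike in both replicates. The stretch of 28S from 2401 to 2800 and the 3 windows of 18S that did not pass were chosen after their values were seen. Alternatives were library totals, DESeq2 size factors or the 28S total in place of TMM, DESeq2 1.42.0 in place of edgeR, windows of 25 and 100 nt, no count filter, the middle position of each window, other flanks and pseudocounts, leaving out the 1% deepest positions, and each eCLIP replicate left out. Scaling to 5S, and windows with Input under 4000 only, were added after seeing the data. Other statistics used Python 3.11.15 with scipy 1.17.1.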

Results

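The RNA contacts of METTL5, the methyltransferase that places N6-methyladenosine (m6A) near the 3′ end of 18S ribosomal RNA, were profiled by eCLIP in 293T cells, a line derived from human embryonic kidney. In eCLIP, protein and RNA are crosslinked with UV light, the protein is immunoprecipitated, and the RNA that stays attached is sequenced. The table covered 4 mature rRNAs: 5S (121 nt), 5.8S (158 nt), 18S (1869 nt) and 28S (5070 nt). It held 2 libraries immunoprecipitated through the HA tag from cells that stably express METTL5-HA, and 1 Input library labelled as wild type. Each value was the number of reads covering 1 position. Mean depth was 2435 reads per position in eCLIP replicate 1, 960.2 in eCLIP replicate 2 and 5927 in Input. No position of any library reached 8000 reads. The maxima were 7465, 7672 and 7986, and 88.7% of Input positions lay at 4000 or more, against 27.3% in eCLIP replicate 1 and 3.38% in eCLIP replicate 2. The plot of depth along both rRNAs shows long level stretches of Input. If reads beyond the ceiling were not recorded, ratios to Input scaled to 5S are upper bounds on 18S, where eCLIP depth lay well below it. Ratios scaled to library totals or by TMM have no known bound, since the scaling itself depends on the ceiling. 5S and 5.8S stayed far below it, at no more than 860 and 1157 reads in any library.

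**Figure D1:**
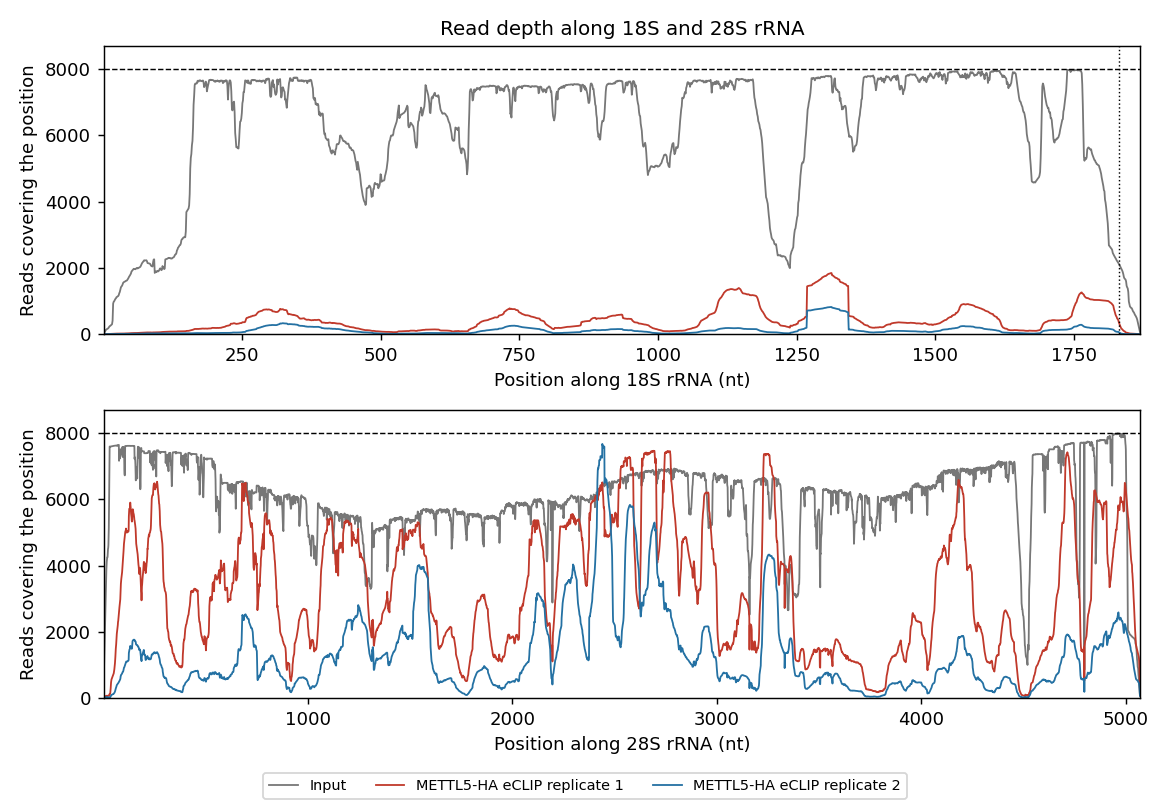
Number of reads covering each position (y axis, linear) along 18S (top) and 28S (bottom) rRNA for Input (grey) and METTL5-HA eCLIP replicates 1 (red) and 2 (blue). The dashed line marks 8000 reads, which no library reached, and the dotted line marks the m6A site at position 1832 of 18S; the eCLIP libraries reach at most 1843 and 818 reads on 18S and 7465 and 7672 on 28S.

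The first comparison asked which rRNA the METTL5-HA reads lay on. In eCLIP they lay almost entirely on 28S, the large-subunit rRNA, which took 95.9% ± 0.932 (SD, n = 2) of summed depth, against 72.5% in Input. 18S, the small-subunit rRNA that carries the METTL5 site, took 3.94% ± 0.909 (SD, n = 2), against 27.1% in Input. The log2 ratio of its share in eCLIP to that in Input was -2.57 in replicate 1 and -3.04 in replicate 2. 5.8S, which pairs with 28S in the large subunit, took 0.006% ± 0.00236 (SD, n = 2), against 0.237% in Input. 5S, the separately transcribed rRNA of the large subunit, took 0.131% ± 0.02 (SD, n = 2), against 0.151% in Input. Exact 95% binomial intervals for the 18S share, with summed depth divided by the 75-nt span of a read, were 4.50% to 4.67% in replicate 1, 3.18% to 3.41% in replicate 2 and 27.01% to 27.2% in Input. The corresponding 28S intervals were 95.2% to 95.3%, 96.5% to 96.7% and 72.4% to 72.6%. These intervals cover counting error only, and reads that are copies of 1 molecule would make them too narrow. If recorded depth was limited, the limit would act on both 18S and 28S in Input, and the Input shares would depend on it. With 1 Input library the shares have no replicate check and no p-value.

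Because 5S was far from the ceiling in every library, mean depths were also set against that of 5S. 18S had 2.05 and 1.83 times the mean depth of 5S in eCLIP replicates 1 and 2, against 11.7 times in Input. The log2 ratio of eCLIP to Input was -2.59 ± 0.115 (SD, n = 2). 18S stayed below the ceiling in both eCLIP libraries, at no more than 1843 reads, and reads missing from 18S in Input would make this ratio too high, not too low. 5.8S, uncapped in all libraries, had 0.0405 and 0.0284 times the mean depth of 5S in eCLIP and 1.20 times in Input, a log2 ratio of -5.15 ± 0.362 (SD, n = 2). Only about 18 reads in eCLIP replicate 1 and 4 in replicate 2 lay on 5.8S, against about 1350 in Input. 28S had 15.7 and 19.7 times the depth of 5S in eCLIP and 11.5 times in Input. The 28S ratio of eCLIP to Input was 0.61 ± 0.235 on the log2 scale (SD, n = 2). The direction of its error is not known, since a ceiling could have removed 28S reads from Input and from eCLIP. Of 28S positions, 94.9% lay at 4000 reads or more in Input, 38.8% in eCLIP replicate 1 and 4.81% in eCLIP replicate 2. Within the eCLIP libraries 28S was covered 7.66 and 10.8 times as deeply as 18S. Those ratios would be larger if 28S reads were lost at the ceiling. In Input the recorded ratio was 0.985, with mean depths of 6210 reads on 18S and 6117 on 28S.

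**Figure D2:**
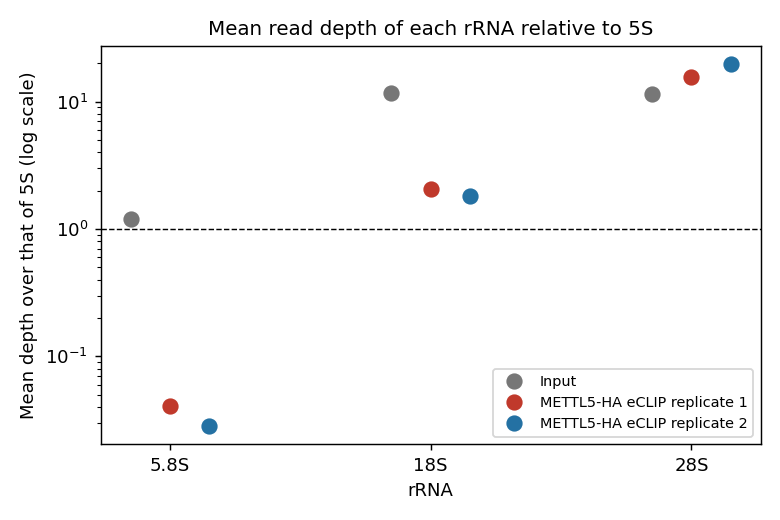
Mean read depth of 5.8S, 18S and 28S rRNA divided by that of 5S (y axis, log scale) in Input (grey) and METTL5-HA eCLIP replicates 1 (red) and 2 (blue), 1 point per library. In eCLIP 18S stands at 2.05 and 1.83 and 5.8S at 0.0405 and 0.0284, below their Input values of 11.7 and 1.20.

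The second comparison located the difference along the rRNAs in 147 windows of 50 nt. At an adjusted p under 0.05 (edgeR quasi-likelihood test, TMM scaling, Benjamini-Hochberg over all windows), 51 windows were lower in eCLIP than in Input and 5 were higher. All 4 windows of 5.8S and 35 of the 38 windows of 18S were lower, and none of either was higher. On 28S 12 of 102 windows were lower, 5 were higher and 85 did not pass. None of the 3 windows of 5S passed, 0 of them at an unadjusted p under 0.05 and 0 with DESeq2. DESeq2's test called 0 windows of 18S higher and 33 lower, and 52 windows of 28S higher and 19 lower. The median log2 fold change of the 18S windows was -2.91 in replicate 1 and -3.17 in replicate 2, and that of the 28S windows 0.61 and 0.46. The median edgeR log2 fold change of all windows was -0.16 with TMM, and -0.58 and -0.98 when scaled to library totals and to the 28S total. The test had 1 residual degree of freedom and assumes that Input varies like the eCLIP libraries. Input stayed under 4000 reads in 9 of the 51 lower windows and 1 of the 5 higher windows.

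Merging adjacent windows left 10 lower and 3 higher regions. Among regions covered in all libraries, the lowest mean log2 fold changes were those of 5.8S from 1 to 158, with values of -4.57 and -4.84 in the 2 replicates. On 18S, positions 1 to 1250 were lower throughout (-3.05 and -3.30; mean depth 346.8 and 90.0 reads against 6033), as were positions 1351 to 1800 (-2.65 and -2.89; 467.3 and 115.6 reads against 7210). The last 19 nt of 18S, 1851 to 1869, had mean depths of 9.74 and 0 reads in eCLIP and 539.8 in Input. A count of 0 allows up to 3 reads. Its summed counts of 185 and 0 in eCLIP came from depths of at most 17 and 0 reads. This region passed edgeR's test (adjusted p = 6.71e-12) but not DESeq2's (log2 fold change -5.14, adjusted p = 0.345). With windows under 4000 in Input fitted alone and scaled to 5S, it also did not pass edgeR's test (-5.43, adjusted p = 0.274). Its adjusted p ranged from 1.42e-26 to 0.345 over the settings run. On 28S the lower regions were 1 to 50 (-2.96 and -3.61), 3651 to 3850 (-1.98 and -2.38), 1751 to 1800 (-1.31 and -1.92), 4451 to 4600 (-1.68 and -1.43), 351 to 400 (-1.09 and -1.59) and 4301 to 4400 (-0.88 and -1.34). In the first of these, 28S positions 1 to 50, mean depths were 235.9 and 44.7 reads in eCLIP and 5289 in Input. When scaled to library totals, at least 1 window no longer passed in 18S 1351 to 1800 and in 28S 3651 to 3850, 4451 to 4600 and 4301 to 4400, although their mean edgeR log2 fold changes went from -2.76, -2.15, -1.54 and -1.09 to -3.18, -2.56, -1.99 and -1.49. At least 1 window was also lost with DESeq2's size factors in 28S 4451 to 4600 (log2 fold change -1.37, edgeR adjusted p = 0.066) and 4301 to 4400 (-0.93, adjusted p = 0.060). The same held for 28S 3651 to 3850 with the middle position (-2.41, edgeR adjusted p = 0.069) and for 18S 1 to 1250 with DESeq2's test (-2.99, adjusted p = 0.11).

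The 3 higher regions all lay on 28S. The 3′ end, 5001 to 5070, had mean log2 fold changes of 2.14 and 2.39 and mean depths of 3367 and 1143 reads against 2089 in Input. Positions 1251 to 1300 had values of 1.35 and 2.30, and positions 3301 to 3400 of 1.16 and 1.66. Mean depths were 3816 and 2183 reads against 4296 in Input at 1251 to 1300. At 3301 to 3400 they were 3207 and 1336 against 4105. Scaled to library totals or to the 28S total in place of TMM, 1 of these 5 windows passed, 5001 to 5050 (edgeR adjusted p = 0.0089 and 0.045), while DESeq2's test called 52 windows higher, these 5 among them. The mean edgeR log2 fold changes of 5001 to 5070, 1251 to 1300 and 3301 to 3400, 2.27, 1.90 and 1.44 with TMM, were 1.82, 1.41 and 0.97 with library totals and 1.42, 1.0 and 0.57 with the 28S total. The window from 3301 to 3350 also did not pass when scaled to 5S (edgeR adjusted p = 0.057), an alternative chosen after seeing the data. Input depth went from 7618 reads at position 5000 to 1838 at 5033. The called windows did not hold the largest fold change of 28S. Window 2401 to 2450 had an edgeR log2 fold change of 2.67 and was not called (edgeR adjusted p = 0.405). Window 3251 to 3300, with 2.16, was also not called (edgeR adjusted p = 0.251). The called windows 5001 to 5050 and 5051 to 5070 had 2.32 and 2.22. At 2401 to 2450 and 3251 to 3300, which were deeper, edgeR's negative binomial trend gave dispersions of 0.123 and 0.114. It gave 0.082 at 1251 to 1300 and 0.051 at 3351 to 3400. The quasi-likelihood dispersions of the test were not recorded, so why the deeper windows were not called cannot be read from these values.

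Among all runs of 8 adjacent windows on 28S, positions 2401 to 2800 held the largest share of 28S depth in each eCLIP replicate. Single windows outside it were deeper than some within it, such as 4701 to 4750 in replicate 1 (6661 reads) and 3251 to 3300 in replicate 2 (3939 reads). The stretch is 7.89% of the length of 28S and held 14.6% of its summed depth in replicate 1, 24.5% in replicate 2 and 8.58% in Input. Mean depths there were 6100 and 4107 reads in eCLIP and 6655 in Input. Of its 8 windows, edgeR called 0 higher, with 0 at an unadjusted p under 0.05, and DESeq2 called 5 higher. The window from 2401 to 2450 had log2 fold changes of 1.49 and 3.31 in replicates 1 and 2 (edgeR adjusted p = 0.405), with mean depths of 6135 and 6454 reads against 6273 in Input.

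Only 3 windows of 18S did not pass the test. Those from 1251 to 1300 (log2 fold change -0.98 and -0.37 in replicates 1 and 2, adjusted p = 0.163) and from 1301 to 1350 (-0.71 and -0.14, adjusted p = 0.364) held the deepest 18S coverage in replicate 2, and the latter also in replicate 1. The remaining window, 1801 to 1850, holds the METTL5 site (-0.63 and -1.58, adjusted p = 0.0948). All p-values are from the edgeR test.

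The third comparison concerned the METTL5 site itself, position 1832 of 18S, 37 nt before the last base. It was covered by 303 reads in eCLIP replicate 1, 48 in replicate 2 and 2087 in Input. In the 51 nt around it, 1807 to 1857, the log2 ratio of eCLIP to Input was -0.71 in replicate 1 and -1.70 in replicate 2, with a mean of -1.21 ± 0.70 (SD, n = 2, TMM scaling). Against the rest of 18S the site stood high: 95.8% of the 1819 windows of 51 nt along 18S had a lower ratio in replicate 1, and 86.2% in replicate 2. Scaled to the total of 18S in place of TMM, the ratio was above 0, at 1.15 ± 0.651 (SD, n = 2). The eCLIP depth at the site did not stand out along 18S, lying above that of 45.5% and 36.3% of 18S positions, while Input depth lay above that of only 7.01%.

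Coverage fell from the METTL5 site towards the 3′ end. At position 1842, acetylated by NAT10, 77 and 2 reads remained in eCLIP against 1664 in Input. At positions 1850 and 1851, the pair of adenosines dimethylated by DIMT1, replicate 1 had 17 reads at each, replicate 2 had 0 at each, and Input had 901 and 833. The last 100 nt of 18S had a log2 ratio of -1.20 ± 0.594 (SD, n = 2). Of the 3 windows that overlap them, 2 were lower after adjustment over all windows and 3 when adjusted over the list alone.

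**Figure D3:**
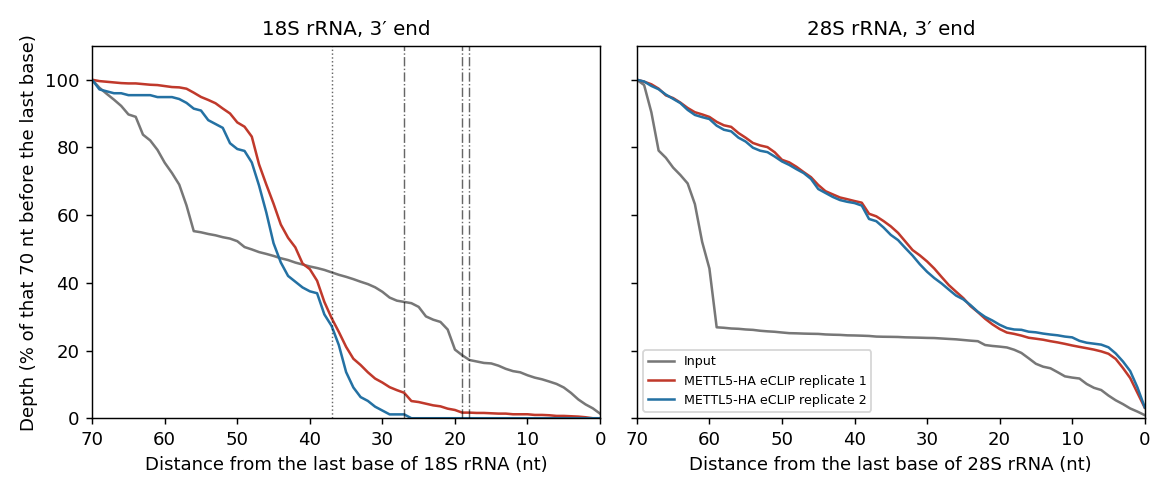
Read depth over the last 70 nt of 18S (left) and 28S (right) rRNA as a percent of the depth 70 nt before the last base (y axis), by distance from the last base (x axis, nt), for Input (grey) and METTL5-HA eCLIP replicates 1 (red) and 2 (blue). The dotted line marks the m6A site and the dash-dotted lines the acetylated and dimethylated bases of 18S. At the m6A site 29.6% and 27.3% of the eCLIP depth remained, and on 28S at the same distance 59.7% and 58.2%. In Input the order was the other way, with 43.1% on 18S and 24.1% on 28S.

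The eCLIP replicates had like profiles. Across the 147 windows, which are not independent replicates, log2 depth correlated with Pearson's r = 0.969 and Spearman's rho = 0.965, and within 28S and 18S windows alone with r = 0.922 and 0.932. The log2 ratios to Input correlated with r = 0.953 over all windows, 0.7999 within 18S and 0.924 within 28S, but both share the same Input. Simulated libraries without enrichment that shared 1 Input gave a mean r of 0.495 over all windows in 100 simulations. The covariance of the ratios was 4.07 over all windows of the data, 1.58 within 18S and 1.38 within 28S, and 0.191 in the simulations. The simulated windows shared no reads with their neighbours. No simulated value was computed within 18S or 28S alone, so the correlations there have none to be set against. No batch was named in the labels, and no untagged immunoprecipitate was among the libraries analysed, so the background of the pulldown was not measured here.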

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

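The alternatives with 5S scaling, and those with Input under 4000, were chosen after seeing the data. The number of lower windows, 51, lay between 45 and 56 under the other scalings, DESeq2, no filter, the middle position and 5S scaling. They numbered 106 of 290 windows of 25 nt, 25 of 74 windows of 100 nt, and 7 of the 13 windows with Input under 4000 when fitted alone and scaled to 5S, where 9 were lower with all windows and TMM. The number of higher windows, 5, was 1 with library totals, 1 with the 28S total, 52 with DESeq2's Wald test, 22 of 290 with windows of 25 nt, 13 of 74 with windows of 100 nt, 8 with the middle position and 1 among windows with Input under 4000. The cause was not tested. The ratio at the m6A site, -1.21, was -1.64 with 10 nt and -1.20 with 50 nt on either side. With 1 eCLIP replicate left out it was only the value of the other, -1.70 or -0.71, and with the 28S total it was -2.06. It turned to 1.15 with the 18S total, which by construction sets the site against the rest of 18S. The log2 ratio of the 18S share, -2.80, kept its sign under all alternatives run. With 1 replicate left out it was only the value of the other replicate, -3.04 or -2.57. The correlation of the ratios between replicates was 0.970 with windows of 100 nt. Of 93 results for named regions under alternatives, 76 kept their direction and call. Another 17 kept their direction and lost the call in at least 1 window, and none reversed. The count filter removed no window, so the 13 results without it, all among the 76, could not differ. Leaving out a replicate leaves no residual degrees of freedom, so the window counts could not be recomputed. No paired analysis was possible because Input has 1 library and no replicate number. Depth limits 5.8S in eCLIP (18 and 4 reads), and a ceiling, if there was one, would limit all ratios on the Input plateau.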

Other observations

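All tests in this part were chosen after the results were seen. Both eCLIP libraries held a block of coverage on 18S with sharp edges. Depth rose from 534 to 1439 reads between positions 1268 and 1269 in replicate 1, and from 191 to 710 in replicate 2. It fell again by 902 and 522 reads after position 1343. The rise equals 8.43% and 17.0% of all 18S reads in the 2 libraries. Input rose by 260 reads at that base, from 6270. The block is 75 nt long, the span taken for a read. On 18S that span was itself found from matched steps, of which those of this block are the largest. The match there is therefore no separate evidence, though 28S gave the same span. It lies in the 2 adjacent 18S windows, 1251 to 1350, that were not called lower. With the step taken out, the log2 ratios of replicates 1 and 2 would be -1.98 and -1.81 at 1251 to 1300. At 1301 to 1350 they would be -1.75 and -1.74. The medians of all 18S windows were -2.91 and -3.17. On 28S the largest single-step rise of replicate 2 was at position 2376, from 1245 to 2430 reads, where replicate 1 rose from 4575 to 5447 and Input changed from 5946 to 5903. At 4 single positions of 28S, namely 2196, 3160, 3506 and 4798, depth was under 80% of the median of the 11 positions centred there in all 3 libraries. The deepest dip was at 4798, with 34.1%, 32.5% and 11.04% of that median in eCLIP replicates 1 and 2 and Input.

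The level Input depth may come from a limit on the depth recorded per position. No position of any library reached 8000, and the longest stretch of 28S that stayed within 5% of its first value was 332 nt in Input, against 53 nt in eCLIP replicate 2. That Input stretch, 2529 to 2860, lay well below 8000. Mean Input depth was 6699 to 6843 reads in the windows from 2551 to 2800. eCLIP replicate 1 reached 7465 reads at position 2690, within the stretch. Of 7218 Input positions, 1952 reached 7000 reads. In eCLIP replicate 1, 683 of 7218 positions lay within 10% of Input and 140 exceeded it by more than 10%, 58 of them in the 28S 3′ end after position 5000, against 30 and 36, with 3 of them there, in eCLIP replicate 2. How such a limit would level Input below 8000, and how many reads Input held beyond it, stay open. No biological explanation was tested.

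If that limit only removed reads at deep positions, it can only raise the ratio of 18S to 5S. The low 18S coverage in eCLIP would then not come from it. The ratio was -2.59 on the log2 scale, with 18S in eCLIP and 5S in all libraries far below 8000. How the limit acted is not known, so this rests on that assumption. Counting error of 5S is too small if its reads are independent molecules, since the exact 95% Poisson bound of its depth of 108 reads in eCLIP replicate 2 lay 0.29 away on the log2 scale, but copies of 1 molecule would widen that bound and stay open. Where Input stayed under 4000 reads, the 5S-scaled log2 ratios went both ways on 28S, with -4.36 and -4.10 at positions 1 to 14 and 1.87 and 2.09 at 5051 to 5070, against -4.03 and -4.06 at 18S 1 to 155 and -1.81 and -2.86 at 18S 1201 to 1250. Binding of METTL5, the rRNA that beads hold without METTL5-HA, and the other genotype of the Input cells stay open and were not tested.

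The eCLIP coverage of 18S thinned before the 3′ end: depth 18 nt before the last base was 5.61% of that at the m6A site in replicate 1, whose last covered position was 1867, and 0% in replicate 2, whose last was 1842. On 28S it was 41.8% and 45.0% in eCLIP. The 2 ends also fell unlike in Input, with 39.9% on 18S and 83.9% on 28S. The comparison with 28S therefore cannot exclude a fall towards any 3′ end. Reverse transcription stopping at the DIMT1 dimethyladenosines is a candidate explanation. Input kept 39.9% on 18S, more than eCLIP did, which would argue against it, but 83.9% on 28S, and it reached 7979 reads within 100 nt upstream on 18S, so its profile there may be flattened and this stays undecided. A contact of METTL5 that protects only the RNA upstream of its site was not tested.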
